A study of Mus musculus with 6 samples.

How the data were processed

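The series holds 6 RNA-seq libraries of mouse cartilage from the spheno-occipital synchondrosis, the growth cartilage between 2 bones of the cranial base. Per the labels, the chondrocyte layers were cut from frozen sections by laser microdissection, and RNA was taken up in QIAzol. Libraries were prepared from total RNA with a SMARTer stranded kit for picogram inputs, per the labels. The mice carried Gli1CreERT2, a Cre recombinase active after tamoxifen under control of the Gli1 gene, with a floxed Tomato reporter, and received tamoxifen at postnatal day 3. The age at collection is not given in the sources used here.

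The deposited values are FPKM (fragments per kilobase of transcript, relative to the fragments of the library) for 24346 gene symbols, in 1 column per library, per the file headers. Per the submitters' processing notes, the tools were TopHat2 2.1.1, Bowtie2 2.2.8, SAMtools 0.1.18 and Cuffdiff 2.2.1 with genome build mm10. Their order, the gene annotation, any scaling between libraries and the use of strand in counting are not given in the sources used here. The symbols were unique within each library (0 repeated), so testing each deposited row on its own gives the same values as the main test. No symbol of a mitochondrially encoded gene was listed, so that list could not be tested (0 members).

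The groups are the codes FP and RR in the library titles, 3 libraries each, numbered 11, 14 and 16 in both. The series text describes flat and round chondrocyte layers, but no label spells out the codes, which are therefore kept as codes. Nothing says that libraries came from separate animals, so p-values measure the spread between these samples, which may be technical. A test of whether libraries with the same number deviate together, and a fit with the number as a block, are given with the alternatives.

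Depth was read from the low values. FPKM times transcript length, for symbols with a single GENCODE M21 basic transcript of 1500 to 3000 bp, fell on steps of 1 fragment: 69.5% to 71.6% of values below about 4 fragments were whole within a tolerance of 0.1 fragments, against 20% by chance. On a 2000 bp transcript, 1 fragment was worth 0.129, 0.255 and 0.187 FPKM in FP libraries 11, 14 and 16, and 0.195, 0.299 and 0.176 FPKM in RR libraries 11, 14 and 16. The deepest library was thus 2.32 times as deep as the shallowest, if libraries were not rescaled against each other. The median tested gene had between 22.7 fragments (RR 14) and 54.4 fragments (FP 11). The total number of fragments is unknown. An FPKM of 0 can be a failed estimate: Rpl26, a ribosomal protein gene, was listed at 0 in 5 libraries and at 45.1 FPKM in FP 16. Genes with a 0 are therefore given library by library.

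Values were tested as log2(FPKM + 1) with limma 3.58.1 in R 4.3.3 (lmFit, eBayes with an intensity trend), contrast FP minus RR, two-sided, for the 14789 genes with a mean of at least 1 FPKM over the 6 libraries. Benjamini-Hochberg adjusted p under 0.05 counted as past the threshold. Log2 changes are on this scale, which understates the change of low genes, and fold values are ratios of mean FPKM. A total of 36 gene lists were fixed before the data were examined, as were the tests, the alternatives and the rule for naming genes. The 34 lists with at least 5 tested members were tested with limma's camera at a preset correlation between genes of 0.01, and again with the correlation estimated per list. The fry test was run beside it: its directional p asks whether members move, on balance, one way, and its mixed p whether they change in either direction.

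Named genes are the 12 with the largest rise and the 12 with the largest fall among genes past the threshold whose groups did not overlap and whose mean was at least 5 FPKM. Names starting with Gm, ending in Rik or of small RNAs were left out of these. To them come the 4 members with the smallest p of each list past its camera test, up to 2 of every other list, and a panel of 16 growth plate genes. Of these, 1 gene is not reported here, but stays in the tests and counts. Any other named gene was chosen after its values were seen. Coordinates are those of GENCODE M21 on mm10, and 23310 of the 24346 symbols were found there.

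The fit was tested on simulated data: 10 sets of 14789 genes, 3 libraries against 3, in which genes with a mean above 5 FPKM changed by known amounts. Means were the real ones, and spreads were averaged over genes of similar mean. It recovered 4.2% of genes changed by 1 on the log2 scale, 60.8% of those changed by 2, 97.6% by 3 and 99.8% by 4, and called 0.06% of unchanged genes. Changes near 1 are thus mostly missed in this design, for genes of average spread. Real spreads differ between genes of similar mean, and no effect of the library number was simulated. The rates are therefore only a rough guide to the real fit. A list of 20 genes shifted by 1 passed camera at unadjusted p under 0.05 in 10 of 10 sets, and an unshifted list in 0 of 10. Simulated genes varied independently, whereas the estimated correlation within real lists ran from 0.040 to 0.658. The simulation therefore does not show how often camera passes an unshifted list of correlated genes.

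Alternatives were pseudocounts of 0.1 and 5, no filter and a filter at a mean of 5 FPKM, quantile and median-ratio normalization, and rescaling to a common sum without small RNAs and the 10 genes with the highest mean. Others were leaving out small RNA, Gm and Rik names, the library number as a block or as a random effect, other variance settings, library weights, and leaving out each library or both libraries of a number. A voom fit on fragment numbers estimated from the steps was added after seeing the data.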

Results

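Gene expression was measured by RNA-seq in chondrocyte layers of the mouse spheno-occipital synchondrosis, in 3 FP and 3 RR libraries. The series compares flat with round chondrocytes of this cartilage. Each library lists an FPKM value for 24346 genes. Depth differed 2.32-fold between libraries if they were not rescaled against each other, and 1 fragment on a 2000 bp transcript was worth 0.129 to 0.299 FPKM. Small RNAs took 51.5% to 70.3% of the summed FPKM of a library, and Rpph1, the RNA of ribonuclease P, alone took 23.6% to 41.0%. Across genes, log2 values correlated between libraries of a group at Pearson's r of 0.856 to 0.873 in FP and 0.787 to 0.845 in RR, with genes not being independent replicates. The first principal component held 29.2% of the variance with the FP libraries at -38.5, -32.3 and -34.7 and RR libraries 11, 14 and 16 at 19.5, 76.9 and 9.11, so that RR 14 stood apart. The second held 25.1% and ordered the libraries by number in both groups, with 11 highest and 14 lowest (37.5, -47.5 and -25.5 in FP 11, 14 and 16, and 59.8, -28.3 and 4.05 in RR).

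Of 18 prehypertrophic and hypertrophic chondrocyte markers, 8 were higher in FP than in RR and 0 lower (camera adjusted p = 2.14e-15, adjusted p = 0.15 with an estimated correlation). Col10a1, the collagen X gene of hypertrophic cartilage, reached 344 ± 42.5 FPKM in FP and 7.05 ± 6.03 in RR (SD, n = 3 each), a 48.8-fold difference. Ihh, the Indian hedgehog ligand of prehypertrophic chondrocytes, rose 31.3-fold, from 2.15 ± 1.55 to 67.3 ± 19.9 FPKM. Alpl, the alkaline phosphatase needed for mineralization, rose 19.4-fold, from 8.08 ± 6.89 to 156 ± 15.1 FPKM. In limma, these log2 changes were 5.66 ± 0.47 (SE, adjusted p = 0.00202), 4.5 ± 0.39 (adjusted p = 0.00237) and 4.41 ± 0.52 (adjusted p = 0.00797), and all 3 FP values lay above all 3 RR values for each gene. Of the 18 prehypertrophic and hypertrophic markers, 8 rose and 0 fell, and 11 rose when adjusted over the list alone. The other risers were Panx3, Phospho1, Sp7, Dlx5 and Pth1r. Panx3, a pannexin channel gene, was at 86.8, 22.7 and 36.6 FPKM in FP and at 0.908, 0 and 3.40 in RR. Phospho1, a phosphatase of matrix vesicles, was at 14.6, 11.3 and 11.8 FPKM in FP and at 0.821, 0 and 1.29 in RR. Sp7, the osterix transcription factor, changed by 2.81 ± 0.28, and Pth1r, the receptor of parathyroid hormone-related protein, by 1.82 ± 0.29. Mmp13, Spp1 and Vegfa did not pass, at log2 changes of -0.10 ± 0.90, 0.91 ± 0.86 and -0.55 ± 0.33. The Pth1r call was lost in 5 and the Dlx5 call in 3 of the 6 fits without 1 library (adjusted p up to 0.175 and 0.0729). With a pseudocount of 0.1 the Panx3 and Phospho1 calls ended (adjusted p = 0.0627 and 0.0617), and with voom those of Panx3, Phospho1 and Dlx5 (0.223, 0.104 and 0.10). The list had a median log2 change of 1.93 and passed camera with adjusted p = 2.14e-15, with adjusted p = 0.15 at an estimated correlation and adjusted p = 0.00762 in fry, lost without FP 11, FP 14 or FP 16 (up to 0.0633). Osteoblast and osteocyte markers also passed camera (median 0.35, camera adjusted p = 0.00833, adjusted p = 0.706 with an estimated correlation), but not without RR 14 or RR 16 (adjusted p = 0.0599 and 0.160) or with library weights (0.0644), and their median ran from -0.068 without both libraries numbered 14 to 1.73 with a filter at a mean of 5 FPKM. Of the members, Alpl and Sp7 rose, both also on the hypertrophic list, while Ibsp, on both lists too, was at 140 ± 50.2 against 19.8 ± 19.0 FPKM (adjusted p = 0.0571). Ibsp passed with the library number as a block (limma adjusted p = 0.0280). Col1a1, the main collagen of bone, was at 393 ± 239 FPKM in FP and 456 ± 539 in RR (adjusted p = 0.968). Skeletal muscle markers also passed camera, with a median log2 change of 1.24, 0 of 16 called, adjusted p = 0.559 with an estimated correlation and RR 11 within the FP range.

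In all, 143 of the 14789 tested genes differed between FP and RR, 82 higher and 61 lower in FP, and all 143 had groups that did not overlap. With the library number as a block 271 differed, and with it as a random effect 412. Among all tested genes 16% had such groups, against 10% by chance. The 82 included 1 small RNA and 2 Gm or Rik names, and the 61 included 3 Gm or Rik names. With small RNA, Gm and Rik names left aside, the largest rises on the log2 scale after Col10a1 were those of Fxyd2, a regulatory subunit of the sodium pump (11.3 ± 5.52 to 398 ± 70.5 FPKM), and Ppa1, an inorganic pyrophosphatase (16.9 ± 11.2 to 435 ± 253 FPKM). Smpd3, a neutral sphingomyelinase, rose by 3.84 ± 0.30 and Il17b, a cytokine gene, by 3.79 ± 0.40. Abi3 rose by 4.17 ± 0.53, and its gene overlaps Phospho1 on the opposite strand. Smim5, of a small membrane protein, was at 21.9, 26.7 and 32.7 FPKM in FP and at 0, 0 and 2.13 in RR. Without 1 library the count fell to between 42 genes (without FP 16) and 85 (without FP 11), with 61 without FP 14, 78 without RR 11, 63 without RR 14 and 74 without RR 16, and rescaling without the highest genes turned the split to 79 higher and 91 lower, with the median change of all genes at -0.23 in place of 0.02. Of the 24 genes with the largest changes, 18 passed in each of the 6 fits without 1 library. In the fits without both libraries of a number, only Fxyd2, Smpd3 and Smoc2 of the 24 always passed. Col10a1 and Ihh were lost without both libraries numbered 14 (adjusted p = 0.0588 each). Alpl, Apoe, Pthlh, Comp and Prkg2 were lost without both numbered 14 and without both numbered 16 (up to 0.208, 0.0729, 0.0904, 0.0757 and 0.0729). Panx3 was lost without FP 16 or RR 14 (adjusted p up to 0.0729) and Abi3 without FP 16 (0.0573). The Smim5 call ended with voom (0.0605).

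**Figure D1:**
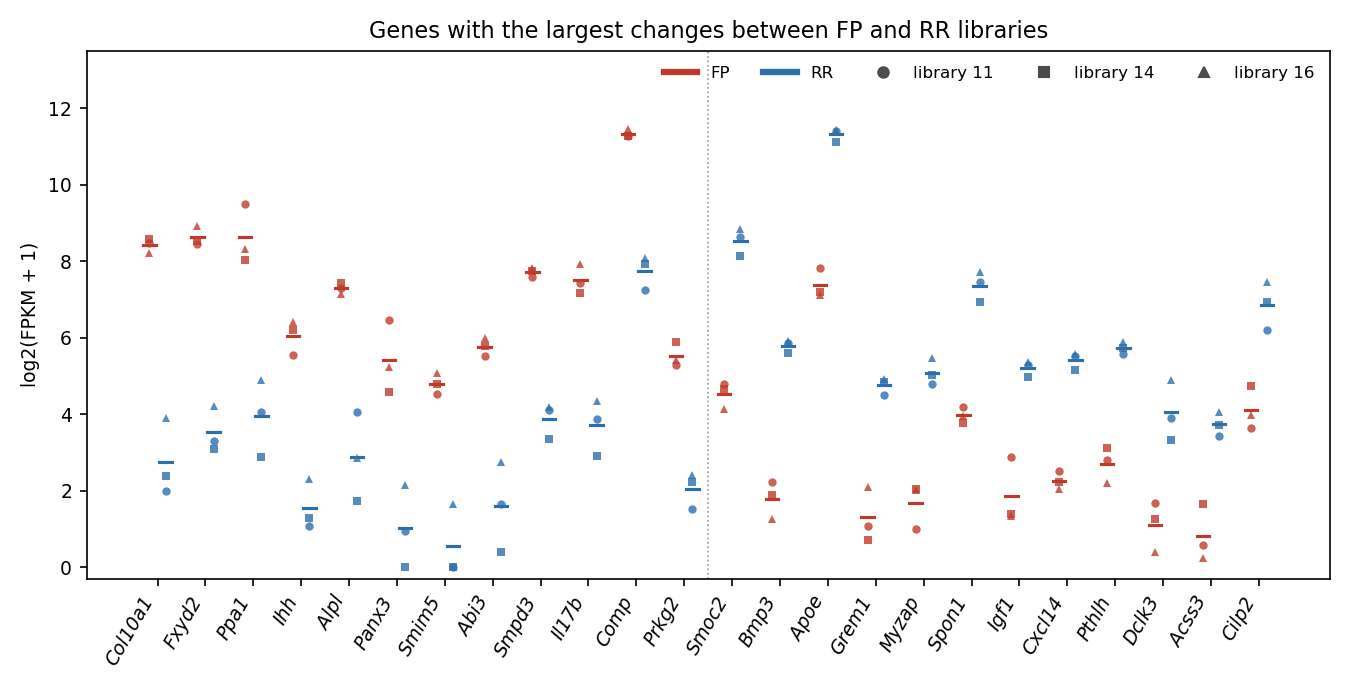
Expression as log2(FPKM + 1) of the 12 genes with the largest rise and the 12 with the largest fall in FP. Each point is 1 library, with colour for the group and shape for the library number, and bars are means of 3 libraries. Col10a1, at the left, averaged 344 FPKM in FP and 7.05 in RR, and Smoc2, the first gene right of the dotted line, 22.5 and 376.

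Of 15 resting zone markers, 6 were lower in FP and 1 higher (camera adjusted p = 1.60e-07, adjusted p = 0.15 with an estimated correlation). Smoc2, a secreted calcium-binding matrix protein gene, was 16.7-fold lower, at 22.5 ± 5.16 FPKM in FP and 376 ± 88.2 in RR (SD, n = 3 each). Apoe, the apolipoprotein E gene, was 15.2-fold lower, at 169 ± 49.5 against 2566 ± 303 FPKM. Pthlh, which codes for the parathyroid hormone-related protein made by resting chondrocytes, was 9.05-fold lower, at 5.75 ± 2.06 against 52.0 ± 5.68 FPKM. In limma, the log2 changes were -4.0 ± 0.31 (adjusted p = 0.00197), -3.95 ± 0.32 (adjusted p = 0.00202) and -3.02 ± 0.30 (adjusted p = 0.00418). Of the 15 resting zone markers, 6 fell (Smoc2, Apoe, Grem1, Spon1, Pthlh and Sfrp5) and 1 rose, Gdf10, a growth factor gene of the BMP family (33.2 ± 19.6 to 260 ± 62.9 FPKM). Adjusted over the list alone, 8 fell and 2 rose, Gdf10 and Foxa2. Foxa2 was at 13.4 ± 5.80 FPKM in FP and 2.78 ± 0.304 in RR (limma adjusted p = 0.0511 over all genes). The Gdf10 call was lost in 4 of the 6 fits without 1 library (adjusted p up to 0.136). Spon1, the spondin 1 gene, changed by -3.39 ± 0.29, and Sfrp5, a secreted Wnt antagonist, by -2.66 ± 0.43, a call lost in each of the 6 fits without 1 library (adjusted p up to 0.106). Without an intensity trend the Sfrp5 and Gdf10 calls ended (0.0545 and 0.0520). Ucma, another marker of the list, was at 399 ± 89.5 FPKM in FP and 614 ± 201 in RR (adjusted p = 0.670). The list's median was -1.80, with camera adjusted p = 1.60e-07, adjusted p = 0.15 with an estimated correlation and 0.00762 in fry, lost without FP 11, FP 14 or FP 16 (up to 0.0633).

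Outside that list, with small RNA, Gm and Rik names left aside, the largest falls on the log2 scale were those of Bmp3, a BMP family member (54.2 ± 6.21 to 2.57 ± 1.14 FPKM), Myzap (-3.40 ± 0.35), Igf1, the insulin-like growth factor 1 gene (36.2 ± 4.99 to 3.16 ± 2.77 FPKM), and Cxcl14, a chemokine gene (-3.17 ± 0.26). Cilp2, of a cartilage intermediate layer protein, fell from 123 ± 52.0 to 17.2 ± 7.28 FPKM, Dclk3, of a kinase, by 2.94 ± 0.47 and Acss3, of an acyl-CoA synthetase, by 2.91 ± 0.40 on the log2 scale. Igf1 was lost without FP 16 or RR 16 (adjusted p up to 0.0602). Cilp2 and Dclk3 were each lost in 4 and Acss3 in 3 of the 6 fits without 1 library (adjusted p up to 0.119, 0.119 and 0.0781). Dclk3 was also lost without an intensity trend (0.0534) and with voom (0.0522). A noncoding gene on the opposite strand inside Smoc2, 4930474M22Rik, also fell, by 3.45 on the log2 scale, at 0.560, 0 and 0 FPKM in FP and 11.1, 7.78 and 18.4 in RR, a call lost with voom (adjusted p = 0.124).

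On mm10, Col10a1 lies on chromosome 10 (34389981 to 34397085), Ihh on chromosome 1 (74945315 to 74951672), Alpl on chromosome 4 (137741733 to 137796384), Smoc2 on chromosome 17 (14279506 to 14404790), Apoe on chromosome 7 (19696109 to 19699188) and Pthlh on chromosome 6 (147252101 to 147264183). Col10a1 sits opposite Nt5dc1, and Igf1 opposite Igf1os. The use of strand in counting is not given, so it is not known whether reads of overlapping exons were separated.

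Of 12 tested columnar chondrocyte markers, 4 were higher in FP and 0 lower (camera adjusted p = 7.35e-12, adjusted p = 0.117 with an estimated correlation). Comp, the cartilage oligomeric matrix protein gene, rose 11.7-fold, from 221 ± 61.6 to 2589 ± 190 FPKM, and Prkg2, the type II cGMP-dependent kinase gene, 14-fold, from 3.28 ± 1.25 to 45.9 ± 11 FPKM (SD, n = 3 each). Epyc, a small leucine-rich proteoglycan gene, rose from 3.24 ± 3.35 to 36.8 ± 14.5 FPKM, and Fgfr3, an FGF receptor gene, from 52.0 ± 16.4 to 170 ± 8.4 FPKM. These 4 of the 12 tested markers rose, with log2 changes of 3.58 ± 0.33 (limma adjusted p = 0.00310), 3.48 ± 0.32 (0.00310), 3.40 ± 0.55 (0.0305) and 1.73 ± 0.29 (0.0341), 0 fell, and 8 rose when adjusted over the list alone. All 12 were higher in FP by their estimate. The median was 1.46, with camera adjusted p = 7.35e-12, adjusted p = 0.117 with an estimated correlation and 0.00762 in fry, lost without FP 11, FP 14 or FP 16 (up to 0.0633). The Epyc and Fgfr3 calls were each lost in 5 of the 6 fits without 1 library (adjusted p up to 0.106 and 0.194). Epyc was also lost with a pseudocount of 0.1, without an intensity trend and with voom (0.0533, 0.0583 and 0.0512), and Fgfr3 without an intensity trend (0.0612).

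Of 24 cartilage matrix genes, Comp and Col6a3 rose and Dcn, the decorin gene, fell, with 19 higher in FP by their estimate and 8 up and 2 down when adjusted over the list alone. Col6a3, a collagen VI chain, went from 49.3 ± 7.54 to 332 ± 52.9 FPKM, and Dcn from 216 ± 73.9 to 51.9 ± 11.8 FPKM. Col6a1, another chain of collagen VI, was at 387 ± 39.8 FPKM in FP and 137 ± 34.6 in RR (limma adjusted p = 0.0674, and 0.0172 with the library number as a block). Col2a1, the main cartilage collagen, was at 61637 ± 17930 FPKM in FP and 61231 ± 21650 in RR (log2 change 0.03 ± 0.59), and Acan, the aggrecan gene, at 1757 ± 383 and 941 ± 337 FPKM (adjusted p = 0.456). The list's median was 0.91, with camera adjusted p = 1.73e-06 and adjusted p = 0.458 with an estimated correlation. The Dcn call was lost in each of the 6 fits without 1 library (adjusted p up to 0.200) and without an intensity trend (0.0612). Of 21 genes of glycosaminoglycan synthesis and sulfation, 1 rose, Slc35d1, a transporter of nucleotide sugars (10.3 ± 2.55 to 37.4 ± 7.14 FPKM), and 3 rose and 1 fell when adjusted over the list alone. Chst3, Slc26a2 and Ugdh did not pass, at log2 changes of -1.35, 1.28 and 1.39. The list's median was 0.42, with camera adjusted p = 0.000938 and adjusted p = 0.559 with an estimated correlation. The Slc35d1 call was lost in each of the 6 fits without 1 library (adjusted p up to 0.136), without an intensity trend (0.0591) and with voom (0.0692).

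**Figure D2:**
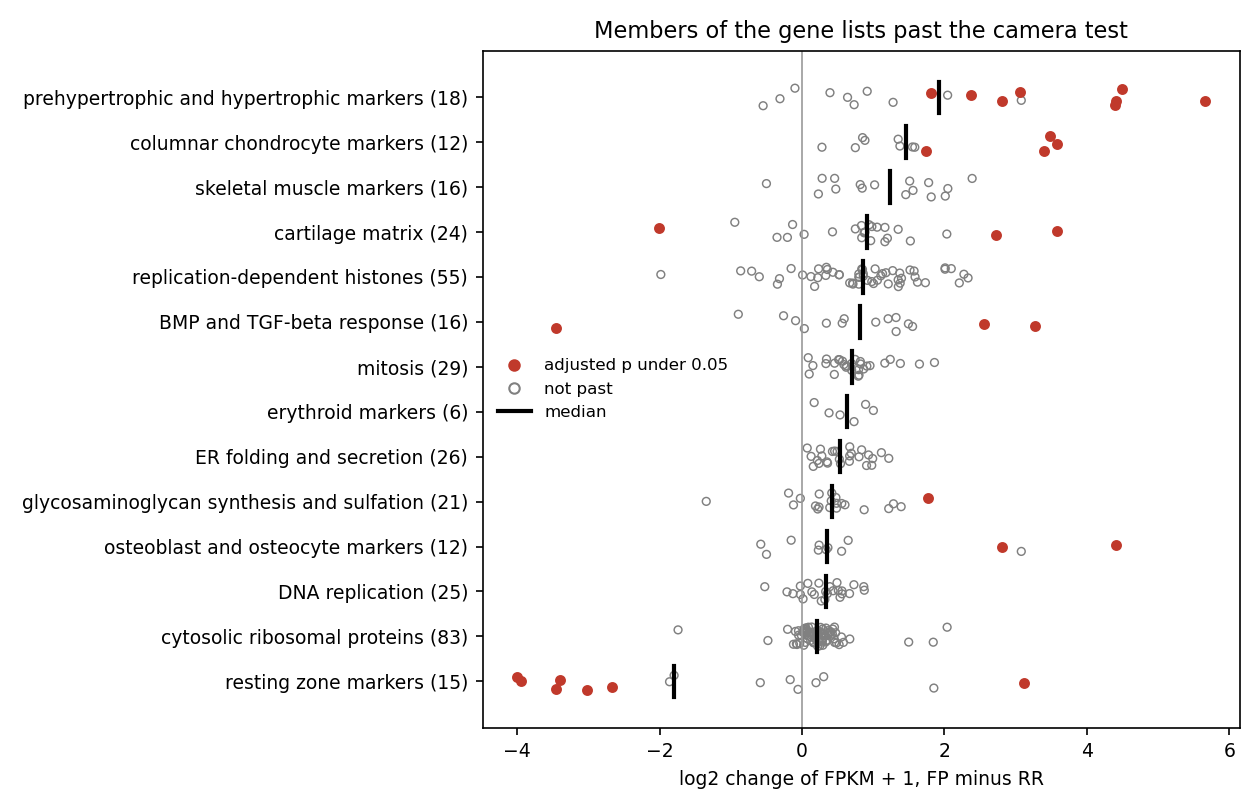
Log2 changes of FPKM + 1, FP minus RR, of the members of the 14 gene lists past the camera test, with the number of tested members in brackets. Filled points passed adjusted p under 0.05 over all genes, open points did not, and bars are medians, from 1.93 for the hypertrophic list to -1.80 for the resting zone list.

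Genes of signalling pathways moved in both directions. Of 16 BMP and TGF-beta response genes, Nog, the noggin antagonist, rose from 0.838 ± 0.384 to 16.9 ± 4.85 FPKM and Id3, a BMP target, from 9.41 ± 3.84 to 61.1 ± 26.2 FPKM, while Grem1, the gremlin antagonist, fell from 26.1 ± 4.12 to 1.67 ± 1.40 FPKM (SD, n = 3 each). Adjusted over the list alone, 8 rose and 1 fell. Atoh8 was at 12.9 ± 3.62 and 4.46 ± 0.711 FPKM (limma adjusted p = 0.0881). The median was 0.81, with camera adjusted p = 2.67e-05 and adjusted p = 0.482 with an estimated correlation. The Id3 call was lost in 4 of the 6 fits without 1 library (adjusted p up to 0.124), after quantile normalization (0.0652) and without an intensity trend (0.0520). Of 16 hedgehog pathway genes, Ihh rose and 2 fell: Gli2, a transcription factor of the pathway, from 35.2 ± 7.05 to 6.59 ± 0.967 FPKM, and Boc, a co-receptor, by 2.18 ± 0.29 on the log2 scale. Adjusted over the list alone, 4 rose and 5 fell. Ptch1, the hedgehog receptor and target, was at 111 ± 12.5 FPKM in FP and 44.6 ± 18.2 in RR (adjusted p = 0.166), and Gli1 at 16.8 ± 2.91 and 13.4 ± 6.55 (adjusted p = 0.816). Ptch1 passed with the library number as a block (limma adjusted p = 0.0452). The hedgehog list did not pass camera (median 0.07, adjusted p = 0.621) but had a fry mixed adjusted p = 1.84e-05. Gli2 was lost without FP 16 (adjusted p = 0.0512) and Boc without FP 16, RR 14 or RR 16 (up to 0.0929).

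Of the other signalling and regulator lists, none passed camera. Among Wnt targets (median 0.14, camera adjusted p = 0.442) Sfrp5 fell, and Ccnd1 was at 21 ± 6.0 and 8.16 ± 1.29 FPKM (limma adjusted p = 0.138). Wnt5b, a noncanonical Wnt ligand gene, rose from 3.85 ± 1.69 to 22.7 ± 2.86 FPKM on the planar polarity list (median 0.27, adjusted p = 0.116), where Celsr2 stood at -1.59 ± 0.31. Fgfr3 rose on the FGF and ERK list (median -0.02, adjusted p = 0.742), and Fgfr1 was at 19.3 ± 3.83 against 52.8 ± 12.8 FPKM (adjusted p = 0.0758). Foxa3 rose among chondrogenic transcription factors (2.17 ± 0.621 to 8.72 ± 1.59 FPKM; median 0.27, adjusted p = 0.0600), and Foxa2, at a log2 change of 1.85 ± 0.34, missed the threshold (adjusted p = 0.0511). Sox9, the main chondrogenic factor, was at 321 ± 46.2 and 153 ± 47.2 FPKM (adjusted p = 0.216), and Runx2 at 59.0 ± 6.85 and 36.3 ± 12.7 (adjusted p = 0.454). Matrix proteases (median -0.35, adjusted p = 0.362) held 0 called genes, with Timp1 at 1.96 ± 0.51 and Adamts6 at -1.03 ± 0.28. YAP targets (median 0.09, adjusted p = 0.807) held 0 called genes, with Axl at -1.34 ± 0.33 and Ptpn14 at -0.43 ± 0.23. Wnt5b was lost without FP 14 or FP 16 (adjusted p up to 0.0733), and Foxa3 in each of the 6 fits without 1 library (up to 0.198) and in 6 of the 14 other fits with all libraries (up to 0.202). The transcription factor list passed without FP 11, FP 16 or RR 16 (adjusted p = 0.0207, 0.0480 and 0.0216) and the planar polarity list without FP 11 (0.0365). Both also passed without a filter. The transcription factor list passed too after rescaling without the highest genes, and without both libraries numbered 11 or both numbered 16. Neither list passed with an estimated correlation in these fits.

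The lists of mitosis, DNA replication, histone and secretion genes passed camera as higher in FP with 0 genes called, and each was lost with an estimated correlation. All 29 tested mitosis genes had an estimate above 0, with a median of 0.70 and 0 past the threshold, and 4 passed when adjusted over the list alone. Cenpa, of the centromere histone, was at 14.1 ± 4.69 and 3.69 ± 0.689 FPKM (limma adjusted p = 0.0534), Ube2c, a mitotic ubiquitin-conjugating enzyme gene, at 15.6 ± 5.90 and 3.49 ± 1.31 (0.0624), Ccnb2 at 11.6 ± 2.23 and 4.4 ± 1.46 (0.132) and Birc5 at 19.3 ± 4.84 and 7.01 ± 3.09 (0.168). Mki67 was at 32.5 ± 10.6 and 18.2 ± 7.54 FPKM (0.496) and Top2a at 26.4 ± 6.12 and 12 ± 6.22 (0.303). The list had camera adjusted p = 6.60e-11 and adjusted p = 0.482 with an estimated correlation. Replication-dependent histones (55 tested, median 0.86) had camera adjusted p = 4.21e-10 and adjusted p = 0.551 with an estimated correlation, with 0 called and 8 up and 1 down when adjusted over the list alone. Hist1h3a was at 22.8 ± 5.79 and 7.13 ± 3.48 FPKM and Hist1h3f at 13.0 ± 1.86 and 4.99 ± 1.98. Hist3h2ba was listed at 5.31, 3.52 and 1.29 FPKM in FP and at 0 in each RR library, and Hist1h2aa at 0 in each FP library and at 4.20, 4.26 and 1.26 FPKM in RR. Histone copies are nearly identical, so reads can be split between them. DNA replication genes (median 0.33, camera adjusted p = 0.0300, adjusted p = 0.623 with an estimated correlation) held 0 called, with Lig1 at 0.87 ± 0.28, Uhrf1 at 0.87 ± 0.30, Cdt1 at 0.67 ± 0.35 and Tk1 at 0.73 ± 0.40. Folding and secretion genes of the endoplasmic reticulum (median 0.53, camera adjusted p = 1.33e-06, adjusted p = 0.559 with an estimated correlation) held 0 called among 26, and 1 when adjusted over the list alone. Creld2 was at 29.0 ± 1.1 and 12.1 ± 3.18 FPKM, with Xbp1 at 0.98 ± 0.27, Dnajb11 at 0.99 ± 0.34 and Sec61b at 1.11 ± 0.40. Skeletal muscle (median 1.24) and erythroid markers (median 0.63) passed camera beside these lists, with 0 called and adjusted p = 0.559 with an estimated correlation for each. RR 11 lay within the FP range for muscle, and the erythroid list missed the threshold without FP 16, RR 14 or RR 16 (adjusted p up to 0.236). DNA replication missed the threshold without FP 11 or RR 14 (adjusted p up to 0.393), with a filter at a mean of 5 FPKM (0.322) and with library weights (0.0665). With the library number as a block, Ube2c, Birc5 and Hist1h3a passed (limma adjusted p = 0.0127, 0.0347 and 0.0452).

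Cytosolic ribosomal protein genes had a median of 0.22 (camera adjusted p = 0.0160, adjusted p = 0.835 with an estimated correlation), with 0 of 83 called, and the median turned to -0.082 after quantile normalization. Among 10000 random lists of the same size matched on mean expression, the median of 0.22 stood at percentile 22.5. The camera call thus does not set these genes apart from others of similar level. The other lists called higher in FP stood at percentile 98.3 or above. Rps4l was at 16.2 ± 2.25 and 9.79 ± 1.12 FPKM, Rpl7a at 428 ± 46.3 and 292 ± 86.0, Rps27l at 1.5 ± 0.56 and Rpl30 at -1.74 ± 0.66 on the log2 scale, and ribosomal genes have many near-identical pseudogene copies. The list missed the threshold without FP 11, FP 16 or RR 14 (adjusted p up to 0.909), after quantile normalization (0.418) and with a filter at a mean of 5 FPKM (0.510). Car12, a carbonic anhydrase gene, rose from 3.70 ± 1.38 to 35.3 ± 15.2 FPKM on the hypoxia list (median -0.09, adjusted p = 0.621), where Ankrd37 stood at 1.45 ± 0.42. Klf4, a Krüppel-like factor, rose from 2.84 ± 1.08 to 13.3 ± 2.23 FPKM among immediate early genes (median -0.15, mean 0.05, adjusted p = 0.942), with Klf2 at 1.63 ± 0.40. Itga10, a collagen-binding integrin of chondrocytes, rose from 10.4 ± 1.90 to 38.7 ± 6.0 FPKM among integrin and focal adhesion genes (median 0.12, adjusted p = 0.148), with Itga6 at 0.74 ± 0.26. The Klf4 and Itga10 calls were each lost in 5 of the 6 fits without 1 library (limma adjusted p up to 0.128 and 0.124), and that of Klf4 without an intensity trend (0.0525) and with voom (0.0903). No gene was called on the lists of cell cycle inhibitors (median 0.44, adjusted p = 0.116; Cdkn1a 1.62 ± 0.32, Gadd45b 1.12 ± 0.32), glycolysis (0.32, 0.116; Slc16a3 1.13 ± 0.29, Pfkp -0.73 ± 0.27), nuclear OXPHOS genes (0.08, 0.795; Ndufa8 0.76 ± 0.29), heat shock proteins (0.19, 0.293; Hspb1 0.58 ± 0.37, Dnajb1 0.40 ± 0.33) and ciliary assembly (0.03, 0.872; Ift57 0.87 ± 0.37, Ift20 0.67 ± 0.29). Some passed camera without 1 library: glycolysis without FP 14 or RR 16 (adjusted p = 0.0122 and 0.0255), cell cycle inhibitors and integrins without RR 16 (0.0362 and 0.0313), and OXPHOS genes lower in FP without RR 14 (0.0422) but higher without RR 16 (0.0287). Glycolysis also passed with the library number as a block, and glycolysis and integrins without a filter. Glycolysis, cell cycle inhibitors and OXPHOS genes also passed without both libraries numbered 16. With an estimated correlation none of these lists passed in these fits. In fry's mixed test on all libraries, integrins (adjusted p = 0.000109), hypoxia (0.000308), immediate early genes (0.00146) and cell cycle inhibitors (0.00453) passed.

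Markers of other cell types differed from library to library. Skeletal muscle markers had a median log2 change of 1.24 (16 tested, 0 called, camera adjusted p = 4.37e-05, adjusted p = 0.559 with an estimated correlation). Their median log2 values were 2.47, 2.58 and 3.86 in FP libraries 11, 14 and 16 and 3.11, 1.23 and 0.79 in RR libraries 11, 14 and 16, so that RR 11 lay within the FP range. Myh8, a perinatal myosin, was at 10.9 ± 5.52 and 2.17 ± 2.29 FPKM, Myh4 at 1.56 ± 0.49, and Myl1 at 1.81 ± 0.69 on the log2 scale. Actn3 was listed at 2.23, 2.22 and 4.49 FPKM in FP and at 1.31, 0.199 and 0 in RR. Erythroid markers (6 tested, 0 called) had a median of 0.63 (camera adjusted p = 0.0280, adjusted p = 0.559 with an estimated correlation), with Hbb-b1 at 88.5 ± 5.10 and 50.8 ± 25.0 FPKM, Hbb-b2 at 30.8 ± 12 and 15.8 ± 9.01, Hba-a1 at 92.0 ± 22.1 and 73.5 ± 32.7 and Slc4a1 at 2.71 ± 1.18 and 1.28 ± 0.893. Globin genes have near-identical copies. Perichondrium and fibroblast markers (median 0.04, mean -0.22, camera adjusted p = 0.116) included Pdgfrb at -1.17 ± 0.24 and Pdgfra at -0.81 ± 0.28. Camera gave adjusted p = 0.942 for osteoclast (Nfatc1 0.34 ± 0.25, Atp6v0d2 -0.52 ± 0.53), 0.758 for endothelial (Ramp2 0.78 ± 0.34, Kdr -0.77 ± 0.37), 0.493 for myeloid (Mpo -1.39 ± 0.62) and 0.807 for neural and glial markers (S100b -0.58 ± 0.39, Gfap -0.37 ± 0.40), with 0 called genes on each. Tyrobp, on the myeloid list, was listed at 3.80, 0 and 3.68 FPKM in FP and at 4.81, 7.32 and 5.18 in RR. Of 10 listed lymphoid markers, 3 were high enough to be tested, too few for a list test. The muscle list missed the threshold without both libraries numbered 16 (adjusted p = 0.0584), the erythroid list without FP 16, RR 14 or RR 16 (up to 0.236) and after quantile normalization (0.0610), and the osteoblast list without RR 14 or RR 16 (up to 0.160) and with library weights (0.0644). The perichondrium list passed as lower in FP without FP 14 or RR 16 (adjusted p = 0.0296 and 0.0362), and the myeloid list as higher without RR 11 (0.0311). The perichondrium list also passed with a filter at a mean of 5 FPKM, with library weights and without both libraries numbered 14.

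**Figure D3:**
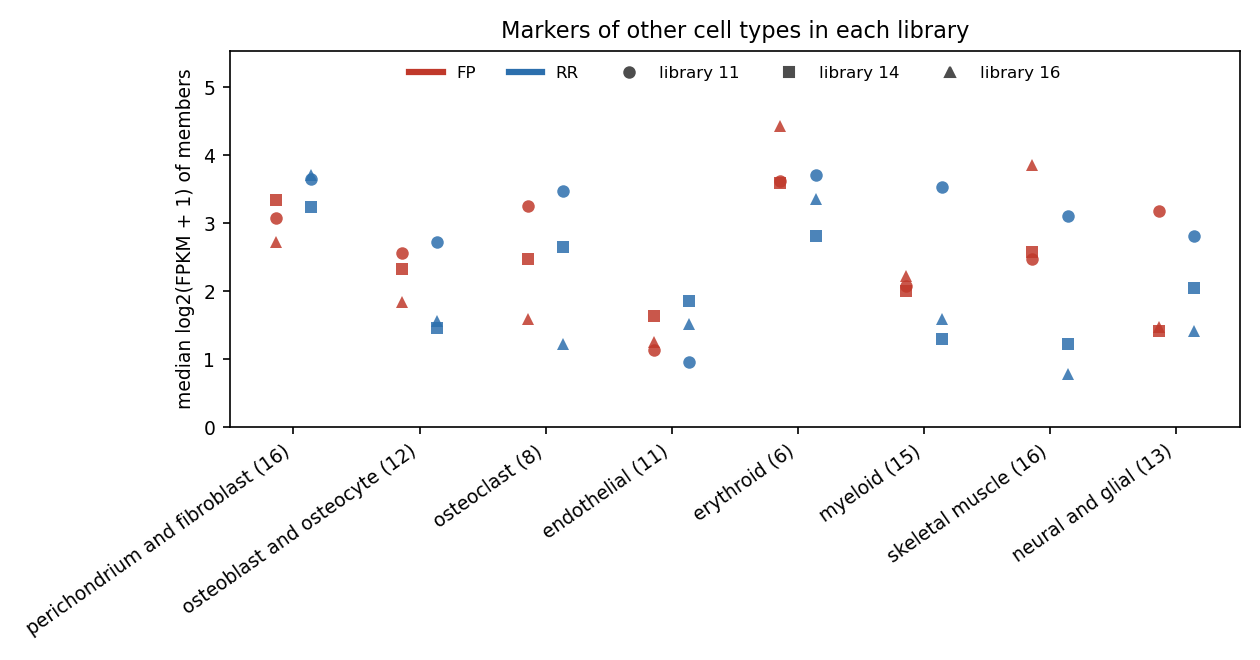
Median log2(FPKM + 1) of the tested members of 8 lists of other cell types, with their number in brackets. Each point is 1 library, with colour for the group and shape for the library number. For skeletal muscle, the 3 FP libraries lay between 2.47 and 3.86, with RR 11 at 3.11 and RR 14 and RR 16 at 1.23 and 0.79.

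Of the 34 lists tested, 14 passed camera, 13 higher and 1 lower in FP. Among the 13, ribosomal proteins had a median no higher than most random lists of matched mean expression. With the correlation estimated per list, 0 passed, the lowest adjusted p being 0.117 for columnar markers. In fry, 3 passed in the directional test (hypertrophic, columnar and resting zone markers) and 18 in the mixed test. Without FP 11, FP 14 or FP 16, 0 passed the directional test (lowest adjusted p = 0.0576, 0.0578 and 0.0633).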

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

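The voom fit on fragment numbers estimated from the FPKM steps was chosen only after the results were seen. The 143 genes kept the sign of their change under all 23 alternatives in which they were tested. All 143 had groups that did not overlap, so leaving out libraries or changing the pseudocount could not turn a sign. The kept signs are therefore no separate support. The count of 143 genes (82 higher, 61 lower) stayed between 115 without a filter and 185 with library weights under the other pseudocounts, filters, scalings, variance settings and voom, except without an intensity trend, which gave 83 (46 higher, 37 lower). Voom gave 136 genes (66 higher, 70 lower), of which 53 and 47 were among the 143. Leaving out libraries, 1 or both of a number, gave 8 to 85 genes, 6 to 56 higher and 2 to 35 lower, with the lowest counts without both libraries numbered 14. Fewer samples enter these fits. The lists past camera numbered 14, and 11 to 18 under the other values and fits and without libraries (not run with voom), 0 with an estimated correlation and 3 in the directional fry test. That test gave 0 without FP 11, FP 14 or FP 16 or both libraries of a number, 3 or 4 without any 1 RR library and 5 with the block. After rescaling without the highest genes, 4 lists passed with an estimated correlation: resting zone (adjusted p = 0.0293), columnar (0.0163), hypertrophic (0.0163) and cartilage matrix (0.0249).

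Libraries with the same number deviated together with r of 0.319 (11), 0.185 (14) and 0.089 (16) across genes, against -0.224 to 0.0461 for other FP and RR pairs. The labels do not say what a shared number means, so the main fit had no block. By these deviations all 6 libraries matched best, in the other group, the library of their own number, a hint from the data and not from the design. With the number as a replicate block, 271 genes differed (160 higher, 111 lower) and 15 lists passed. Of the named genes short of the threshold, Col6a1, Chst3, Slc26a2, Ugdh, Foxa2, Ccnd1, Celsr2, Fgfr1, Axl, Ube2c, Birc5, Hist1h3a, Cdkn1a, Ibsp, Myl1 and Ptch1 passed with the block. As a random effect it gave 412 genes (241 higher, 171 lower), at a consensus correlation within numbers of 0.364. The count of 143 genes thus holds for the fit that leaves the number out.

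The direction turned for 3 lists that were past the threshold in only 1 fit of each pair compared. Ribosomal proteins had a median of -0.082 after quantile normalization and of 0.0011 to 0.37 without libraries, the lowest without RR 14, where the camera direction turned. Myeloid markers had medians of -0.45 to 0.48 without libraries and passed as higher in FP without RR 11 (0.25) and without both numbered 11 (0.33). They passed as lower without both numbered 16. OXPHOS genes had medians of -0.32 to 0.41, with the lowest without RR 14. The cause was not tested. Values past the threshold in neither fit were not compared for direction. Over alternatives, 2398 values of named genes kept their side of the threshold, 83 passed it and 190 fell below it, and for lists these numbers were 695, 26 and 19. Depth limits low genes: 1 fragment on 2000 bp is worth up to 0.299 FPKM.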

Other observations

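The tests of the bone, scaling, pituitary and Mir467f explanations, and the IGF and BMP gene groups, were chosen only after the results were seen. Of 13 tested genes of the insulin-like growth factor axis, 4 fell and 1 rose. Over all 13 the median log2 change was 0.03, while camera pointed lower in FP (unadjusted p = 0.0132, p = 0.0586 with an estimated correlation). Besides Igf1, the binding protein gene Igfbp4 fell from 118 ± 38.4 to 19.8 ± 4.01 FPKM (SD, n = 3 each), Igfbp7 from 171 ± 44.1 to 49.4 ± 4.56 FPKM, and Pappa, a protease that cleaves IGF binding proteins, from 9.50 ± 2.42 to 1.26 ± 0.486 FPKM. Stc2, an inhibitor of that protease, rose from 1.051 ± 0.561 to 8.70 ± 1.70 FPKM. Igf2 was at 418 ± 105 and 492 ± 163 FPKM and Igf1r at 11.6 ± 0.906 and 9.68 ± 2.78 FPKM (limma adjusted p = 0.906 and 0.833). Igfbp7 was lost in each of the 6 fits without 1 library, Pappa and Stc2 in 4 and Igfbp4 without FP 16 (adjusted p up to 0.172, 0.0826, 0.0796 and 0.0828). Igfbp7 was also lost without an intensity trend (0.0534).

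Of 20 tested ligands and antagonists of the BMP and GDF family (median -0.27, camera p = 0.144, p = 0.345 with an estimated correlation), Nog and Gdf10 rose and Bmp3, Grem1 and Gdf5 fell. Gdf5, a growth factor of joint cartilage, fell from 10.7 ± 6.74 to 0.881 ± 0.0953 FPKM (SD, n = 3 each). Bmp6 was at 10.3 ± 5.08 and 1.47 ± 0.860 FPKM (limma adjusted p = 0.0758). The Gdf5 call was lost in 5 of the 6 fits without 1 library (adjusted p up to 0.161) and in 6 of the 14 other fits with all libraries (up to 0.105).

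The 8 hypertrophic genes that rose had a median log2 change of 3.73. Bone tissue in the FP captures may raise such genes, and was not excluded. The osteoblast and osteocyte list had a median of 0.35 (SD 1.58 over 12 members, 3 of them also hypertrophic), 3.38 below the 8 genes, which were chosen for their change, but 1.579 below the median of all 18 hypertrophic markers (1.93), less than 1 SD by a narrow margin. That osteoblast median was unstable, from -0.068 to 1.73 over the alternatives, so the comparison decides nothing. Scaling between libraries was also tested: all 8 stayed past the threshold under the 3 other scalings, with medians of 3.65, 3.70 and 4.21. A difference between the chondrocyte layers themselves stays open and was not tested further.

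Anterior pituitary genes were present in libraries of both groups. Gh, the growth hormone gene, was at 485 and 674 FPKM in FP 14 and RR 14, 281 and 320 in FP 16 and RR 16, and 7.23 and 10.5 in FP 11 and RR 11. Of 12 pituitary genes, 12 were higher in both libraries numbered 14 than in both numbered 11, and 7 in both numbered 16. The list was chosen after these levels were seen and largely restates them, so pituitary tissue in the captures stays open. Reads of a single pituitary library assigned to several libraries would keep the ratio of Gh to Pomc, which instead was 0.639, 2.29, 4.91 and 6.73 in FP 14, RR 14, FP 16 and RR 16, a range of 10.5-fold. No other explanation was tested.

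Mir467f, a microRNA gene, was listed at 1226, 2436 and 1782 FPKM in the FP libraries and at 0 in the RR libraries, with the smallest p of all genes. Divided by the library's FPKM step of 1 fragment times transcript length, these were 4.76, 4.77 and 4.75 fragments per bp, a ratio of highest to lowest of 1.003, so the values may stand for the same number of fragments in each library. That number is unknown, since the length used for this gene is not given. Of 15 small RNAs above 0 in exactly 3 libraries, 1 was above 0 in the 3 FP libraries, with 0.75 expected by chance. No biological explanation was tested.

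The 6 libraries can be split into 3 and 3 in 10 ways, too few for a share under 0.05. Every other split mixes FP and RR libraries on both sides, so an FP to RR difference widens the spread within its groups. Low gene counts and larger p in those splits are therefore no separate support. The real split gave 143 genes and the highest other 5, 82 higher against 4 and 61 lower against 4, each reached in 1 of 10 splits. It gave 14 lists and the highest other 17, and 3 of 10 splits gave at least as many. By list, the unadjusted camera p of the real split was the smallest for hypertrophic (6.30e-17, lowest other 0.000505), columnar (4.32e-13, 0.000365), resting zone (2.35e-08, 0.00725), cartilage matrix (3.57e-07, 0.000315), BMP and TGF-beta response (6.27e-06, 0.00200), mitosis (5.82e-12, 5.92e-09), histone (4.96e-11, 8.61e-11) and glycosaminoglycan genes (0.000276, 0.000385). Other splits gave a p as small for endoplasmic reticulum genes, muscle and erythroid markers (2 each), DNA replication genes and osteoblast markers (3 each) and ribosomal proteins (5).

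Single libraries held high values of genes chosen after they were seen. In FP libraries 11, 14 and 16 and then RR libraries 11, 14 and 16, Ucp1 of brown fat was at 0.799, 2.22, 8.36, 0.243, 1.85 and 131 FPKM and Fabp4 of fat cells at 5.77, 2.08, 31.3, 7.98, 0 and 369. Of airway gland genes, Bpifb1 was at 5.47, 6.07, 1031, 0.978, 0 and 5.71 FPKM, Sbpl at 0.342, 0, 371, 1.56, 0.791 and 1.87, and Scgb1a1, highest in another library, at 3.46, 0, 3.77, 46.1, 2.0 and 0. Neural and glial markers had median log2 values of 3.18 in FP 11 and 2.82 in RR 11, against 1.41 to 2.05 in the other libraries.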
